A study of Mus musculus with 9 samples.

How the data were processed

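The series holds 9 mouse arrays: liver of 3 Notch1 wild-type animals, liver of 3 Notch1 knockout animals and 3 angiosarcoma cell lines derived from knockout mice. The labels give 3 animals per liver group and 3 separately derived lines, so each array was taken as 1 independent replicate. Per the labels' protocols, total RNA was reverse transcribed and biotin-labelled with a whole-transcript kit, and liver was snap-frozen. The deposited values are log2 expression per probe set, and per the submitters' processing notes they were made with RMA and the oligo package; versions are not given in the sources used here. The table holds 35556 probe sets with 0 missing values. Medians per array ran from 6.53 to 6.63, and between 476 and 1614 probe sets had identical values in any pair of the 9 arrays, livers and lines included, as happens after quantile normalization of all arrays together. Such normalization gives all arrays nearly one distribution, so a shift of most genes in one direction cannot be seen. The table has no detection calls: a low value can be background, and a fold change against one understates the difference.

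Probe sets were named from the platform's annotation table. Of the 35556 probe sets, 21789 had 1 gene, 1621 several and 12146 were not in the table. The gene ID of 21698 of the 21789 was found in a RefSeq gene table, which changed 0 symbols. For the 999 genes with more than 1 probe set, the probe set with the highest mean over all 9 arrays was used, which left 19938 genes. Apart from ranks within an array, no level of one probe set was set against that of another.

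Each pair of groups was fitted with limma 3.58.1 (lmFit and eBayes, 2-sided) in R 4.3.3 on the 6 arrays of the comparison, without covariates, with Benjamini-Hochberg adjustment over all 19938 genes and a threshold of 0.05. The fold changes are differences of group means of log2 values. For Notch1, an exact permutation test of the means was added. A set of 44 gene lists for liver cell types, endothelium, Notch, interferon, metabolism and other themes was used; 97 of its 984 entries were not measured. Each list was tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 44 lists of a comparison, and again with the correlation estimated from the data and with fry. Genes past the threshold were counted per list over all genes tested and adjusted over the list alone.

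The lists, the tests, the rule for named genes and the alternatives not named as added were fixed before the data were examined. The rule takes Notch1, and the 10 largest rises and 10 largest falls past the threshold among genes whose groups do not overlap, leaving out predicted genes, Rik and LOC symbols, small RNAs, olfactory and vomeronasal receptors, histone clusters and immunoglobulin or T cell receptor segments. Where fewer than 10 passed, the genes of smallest unadjusted p were taken and are described as not past the threshold. From each list it takes the 3 members of largest absolute log2 fold change. The text names genes from the top of each ranking.

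The alternatives were a replicate block, all 9 arrays in one fit, an intensity trend with robust hyperparameters, a filter on dim genes, scaling to the 75th percentile, repeated quantile normalization, the mean of all probe sets of a gene, all probe sets tested singly, array weights, leaving out each replicate, at least a 2-fold change and an adjusted p under 0.10. A covariate for hepatocyte genes, and leaving out WT replicate 1 together with KO replicate 3, were added after seeing the data.

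The procedure was tested on simulated data for 19938 genes, in which 100 genes were changed by 1 and 100 by 2 log2 units. Values were drawn independently for each gene and array from normal distributions with the gene's own mean and SD. Correlation between genes and shifts shared by an array were left out, so the counts do not give power or error rate in the real arrays. For KO against WT livers it recovered 59 and 84 of them, with 6 unchanged genes called. For AS lines against KO livers it recovered 41 and 69, with 3 unchanged genes called, and for AS lines against WT livers 48 and 74, with 10. Figures were drawn with matplotlib 3.10.9.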

Results

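Gene expression was measured on 9 whole-transcript mouse arrays that fall into 3 groups of 3. The first group, called WT liver here, is liver of mice that carried loxP-flanked Notch1 but no Cre. The second, KO liver, is liver of mice with the same Notch1 allele and MxCre, a Cre switched on by the interferon response. All mice were on a C57Bl/6 background and received 300 µg of poly(I:C), a double-stranded RNA mimic that triggers this response, on days 0, 3 and 6 from the age of 4 weeks. The third group, AS cell line, holds 3 angiosarcoma cell lines grown from liver endothelial cells of Notch1 knockout mice with a visible tumour of that kind, a cancer of vessel-lining cells. The labels give liver as the source of the first 2 groups, but the extraction protocol shared by all 9 arrays names PHH, an abbreviation left unexplained. Whether whole liver or a fraction of its cells was extracted is therefore not settled, and levels of cell type markers hold for the RNA as extracted. Endothelial genes were bright in every liver array, with a median rank of the pan-endothelial list at 95.9 to 98.1 percent of all genes tested. How such a rank reflects the share of endothelial cells was not tested. Values are log2 expression after robust multi-array averaging. After reduction to 1 probe set per gene, 19938 genes were tested, and the number of arrays limits the precision of every value.

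The comparison of KO with WT livers asks what changes in the liver with loss of Notch1, a receptor through which neighbouring cells signal to each other. Only the KO mice carried MxCre, so an effect of Cre itself cannot be told apart from loss of Notch1. Notch1 itself had a mean of 11.47 ± 0.39 (SD, n = 3) in the WT livers and 8.37 ± 0.47 (SD, n = 3) in the KO livers, so that the KO value was 11.6% of the WT value. The highest KO array, at 8.75, lay below the lowest WT array, at 11.02. The log2 difference of -3.10 (SE 0.302) had an adjusted p of 0.0995 in limma over all genes, and the exact permutation test gave 2-sided p = 0.1, the smallest that 3 against 3 arrays allow. The deletion takes out the exon for the signal peptide, and the positions of the probes relative to it were not analysed here. Hes1, a transcriptional repressor switched on by Notch signalling, was 0.76 log2 units lower in the KO livers (SE 0.0901, adjusted p = 0.0995). Sox9, a progenitor and bile duct transcription factor, was lower by a log2 difference of -0.85 (SE 0.127, adjusted p = 0.0995), and the Notch ligand Jag1 by one of -0.72 (SE 0.171, adjusted p = 0.114).

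**Figure D1:**
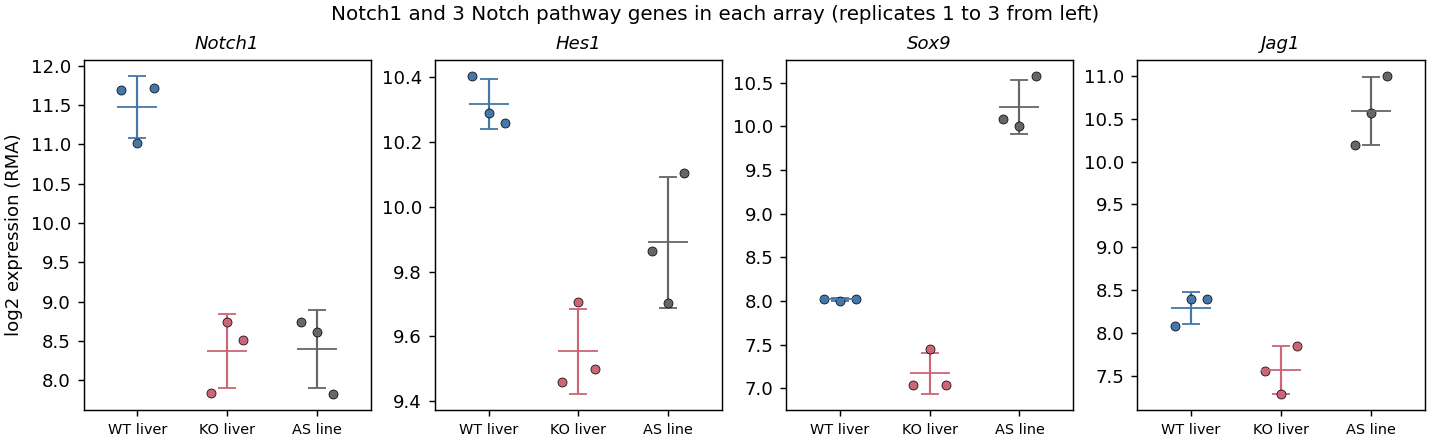
Log2 expression (vertical axes, each with its own range) of Notch1, Hes1, Sox9 and Jag1 in the WT livers, KO livers and AS cell lines. Points are arrays, horizontal bars group means and error bars 1 SD (n = 3). For all 4 genes, the 3 KO points lie below the 3 WT points.

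No gene passed an adjusted p of 0.05 in limma in this comparison: 0 were higher and 0 lower, the smallest adjusted p was 0.0995, and 4479 genes had an unadjusted p under 0.05, against 997 by chance. Of these 4479, 3449 were higher in the KO livers and 1030 lower. The median log2 fold change of all genes moved to 0.15 with dim genes left out and to -0.18 with 75th percentile scaling. The split of directions may therefore depend on the processing. Camera called 20 of 44 lists, 4 higher and 16 lower, and 0 with an estimated correlation, and fry called 0 (smallest adjusted p 0.116). Lists called lower included that of pancreas, skeletal muscle and fat (median -0.10, camera adjusted p = 0.00617), with low means of 5.86 in WT and 5.74 in KO livers. Ribosomal protein genes were called higher at a median of 0.10 (camera adjusted p = 0.0290). A call with the preset correlation can thus rest on a small shift, also of dim genes. Of the gene lists, 2 of 11 Notch receptors and ligands (Notch1 and Jag1) were lower when adjusted over the list alone, and 0 of 11 over all genes tested. Notch4, the endothelial Notch receptor, differed by 0.57 (SE 0.215, adjusted p = 0.204). Of 21 Notch target genes, 2 were lower and 1 higher adjusted over the list alone, with 0 over all genes. Hes1 and Sox9 had list-alone adjusted p-values of 0.00426 and 0.00729. Camera called neither of the Notch lists, with adjusted p = 0.102 for receptors and ligands, and 0.172 for targets. The receptors and ligands were called lower without KO replicate 1 (adjusted p = 0.0383), with dim genes left out (0.0116) and with repeated quantile normalization (0.0201), and the targets with dim genes left out (0.0141). The receptor and ligand list holds Notch1, the targeted gene, so part of its fall is built into the design. Its mean log2 fold change was -0.35 and its median -0.10, and it was not tested without Notch1. Mfng, a glycosyltransferase that modifies Notch receptors, differed by 0.71 (SE 0.203, adjusted p = 0.14). Among the genes of smallest unadjusted p, Rab3b, a vesicle-trafficking GTPase, was higher in the KO livers by 1.86 (SE 0.133) and Cfap97 by 0.82 (SE 0.0760). Ackr1, a chemokine-binding receptor of venules, was lower by a difference of -1.52 (SE 0.104), the chemokine Ccl5 by -1.72 (SE 0.150) and the epithelial cadherin Cdh1 by -1.62 (SE 0.153). Each of these 5 had an adjusted p of 0.0995.

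Genes of the cell cycle were higher in the KO livers. Of 29 measured genes of the proliferation list, 28 had a positive log2 fold change, with a median of 1.36, and in 22 every KO array lay above every WT array and in 0 below. For 1 gene chance gives 10% for the 2 directions together. The share over all genes was not counted and may be higher, since 22.5% of all genes had an unadjusted p under 0.05 in limma. Adjusted over the list alone 23 were higher, and over all genes tested 0. The cyclin Ccna2 differed by 2.06 (SE 0.430, adjusted p = 0.104), the mitotic kinase Plk1 by 2.03 (SE 0.408, adjusted p = 0.102) and the checkpoint kinase Bub1 by 2.01 (SE 0.386, adjusted p = 0.102). Camera called the list higher (adjusted p = 4.43e-10), and the call was lost with adjusted p = 0.83 with an estimated correlation. The mean of the list stood 1.79, 0.59 and 1.46 log2 units above the WT mean in KO replicates 1, 2 and 3. The rise was thus smallest in KO replicate 2, where the hepatocyte list was highest among the KO livers.

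Genes of the cholangiocyte list, which stands for bile duct epithelium, were lower in the KO livers. All 18 measured members of the cholangiocyte list had negative log2 fold changes, with a median of -0.60. Adjusted over the list alone 10 were lower, and over all genes tested 0 (camera adjusted p = 1.48e-08, and adjusted p = 0.83 with an estimated correlation). Besides Cdh1, the keratins Krt8 and Krt18, which hepatocytes also express, differed by -1.83 (SE 0.720, adjusted p = 0.214) and -1.73 (SE 0.984, adjusted p = 0.343). Krt8 was at -1.21 without KO replicate 3, and Krt18 at -0.83 without KO replicate 3 and -2.78 without KO replicate 2. Among the KO livers both keratins were highest in replicate 2, at 11.15 and 11.30, where the hepatocyte list was also highest. The mean of the cholangiocyte list was 7.03 in the WT and 6.33 in the KO livers, against array medians of 6.59 to 6.63. Part of the list may therefore lie near background, and the hepatocyte list fell more (median -1.21).

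Hepatocyte genes differed widely between arrays of one genotype. The mean of the 34-gene hepatocyte list was 10.80, 12.00 and 11.99 in WT replicates 1, 2 and 3 and 9.97, 12.16 and 8.84 in KO replicates 1, 2 and 3. The list had a median log2 fold change of -1.21, with 0 of 34 members lower over all genes and 0 adjusted over the list alone (camera adjusted p = 2.41e-05, and adjusted p = 0.83 with an estimated correlation). Its median was -2.25 without KO replicate 2 and -0.51 without KO replicate 3. Tat and Tdo2, enzymes of tyrosine and tryptophan breakdown, differed by -1.98 (adjusted p = 0.277) and -1.98 (adjusted p = 0.336). Without KO replicate 2 they were at -3.05 and -3.20, and Tdo2 at -1.32 without KO replicate 3. Periportal hepatocyte genes had a median of -1.75, and 1 of 14 members was lower adjusted over the list alone and 0 over all genes (camera adjusted p = 5.98e-05, and adjusted p = 0.83 with an estimated correlation). Their median was -2.80 without KO replicate 2 and -0.85 without KO replicate 3. Cyp2f2, a cytochrome P450 of periportal cells, differed by -3.58 (SE 1.01, adjusted p = 0.139) and the histidine-degrading enzyme Hal by -3.24 (SE 0.921, adjusted p = 0.139). Hepcidin (Hamp), the hormone that limits iron uptake, differed by -3.85 (SE 1.66, adjusted p = 0.244). It stood at 5.46, 11.87 and 6.70 in KO replicates 1, 2 and 3, against a WT mean of 11.86 ± 0.27 (SD, n = 3), and without KO replicate 2 the difference was -5.78. The acute phase list, to which it belongs, had a median of -0.99 with 0 of 26 members lower, over the list alone or over all genes. Its camera call (adjusted p = 0.00383) was lost without KO replicate 3 (median -0.21, adjusted p = 0.212) and with an estimated correlation (adjusted p = 0.83). It was also lost with 75th percentile scaling (adjusted p = 0.175), and the median was -2.13 without KO replicate 2, -1.52 without WT replicate 1 and -0.64 without WT replicate 3.

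Lymphocyte genes were also lower on average. All 22 members of the T and NK cell list had negative log2 fold changes (median -0.98), with 1 of 22 lower adjusted over the list alone and 0 over all genes (camera adjusted p = 2.05e-06, and adjusted p = 0.83 with an estimated correlation). The median was -1.55 without WT replicate 1 and -0.61 without WT replicate 2. Their mean stood 1.12 below the WT mean in WT replicate 1 (-1.12), 0.59 and 0.53 above it in WT replicates 2 and 3, and at -1.08, -1.02 and -0.91 in the KO livers. The granzyme Gzma differed by -1.90 (adjusted p = 0.239) and the T cell receptor component Cd3g by -1.85 (adjusted p = 0.368). Without WT replicate 1 they were at -2.86 and -3.17, and Cd3g at -1.14 without WT replicate 3. Of the B cell and plasma cell list, 17 of 18 had negative log2 fold changes (median -0.43), with 0 lower over the list alone or over all genes (camera adjusted p = 5.24e-05, and adjusted p = 0.83 with an estimated correlation).

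Markers of other liver cells were measured as well. The pan-endothelial list had a median of 0.19 with 0 of 31 members past either adjustment (camera adjusted p = 0.0290, and adjusted p = 0.83 with an estimated correlation). That call ended without WT replicate 2 or 3 (adjusted p = 0.103 and 0.0669) and without KO replicate 1 or 3 (adjusted p = 0.188 and 0.357), with dim genes left out (0.574) and with repeated quantile normalization (0.0749). Its median was 0.33 without KO replicate 2 and 0.08 without KO replicate 3. Its largest difference was that of Plvap, a protein of endothelial pores, at 0.85 (SE 0.358, adjusted p = 0.237). Of 13 genes of arterial and venous identity, 3 were higher and 2 lower adjusted over the list alone, and 0 over all genes (camera adjusted p = 0.309, and 0.0365 without KO replicate 2). The arterial connexin Gja4 differed by -2.25 (SE 0.679, adjusted p = 0.149), the apelin receptor Aplnr by 1.96 (SE 1.01, adjusted p = 0.309) and the venous regulator Nr2f2 by 0.86 (SE 0.166, adjusted p = 0.102). Gja4 was at -1.47 without KO replicate 1, and Aplnr at 1.06 without KO replicate 1 and 3.09 without KO replicate 2. The median was 0.13 for 24 liver sinusoidal endothelial genes, -0.02 for 23 Kupffer cell and macrophage genes, 0.06 for 28 stellate cell and fibroblast genes and 0.09 for 27 interferon-stimulated genes. Camera called none of these 4 lists (adjusted p = 0.309, 0.442, 0.833 and 0.538). Without KO replicate 2 the Kupffer list was called lower (median -0.21, adjusted p = 0.00753), as with dim genes left out (0.0254), and without KO replicate 1 the interferon list higher (median 0.21, adjusted p = 0.0383). Adjusted over the list alone, 2 sinusoidal genes were higher and 0 of the other 3 lists, and 0 of all 4 passed over all genes. Among 16 pan-leukocyte genes the median was -0.26, with 0 past either adjustment (camera adjusted p = 0.0113, and adjusted p = 0.83 with an estimated correlation). This call ended without WT replicate 3 (adjusted p = 0.0606) or KO replicate 1 or 3 (adjusted p = 0.0820 and 0.0754), and the median was -0.17 without WT replicate 1, -0.12 without KO replicate 1 and -0.48 without KO replicate 2. Of 19 genes named in angiosarcoma, 6 were higher adjusted over the list alone and 0 over all genes, with a median of 0.31 (camera adjusted p = 0.00383, and adjusted p = 0.83 with an estimated correlation). That call was also lost with dim genes left out (adjusted p = 0.124). The largest difference of that list was that of the growth regulator Myc, at 0.63 (SE 0.114, adjusted p = 0.0995, and 0.0134 over the list alone).

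The animals also differed in sex-linked expression. The Y-linked translation factor gene Eif2s3y stood at 8.66 and Uty at 8.35 in KO replicate 3, and at most at 4.02 and 4.28 in the other 5 livers. The Y-linked list had 0 of 6 members past either adjustment (camera adjusted p = 0.401). Genes biased to female liver had a median of -1.03, with 1 of 19 lower adjusted over the list alone and 0 over all genes (camera adjusted p = 0.0290, and adjusted p = 0.83 with an estimated correlation). The call ended without WT replicate 2 or 3 (adjusted p = 0.0901 and 0.165) and without KO replicate 1 or 3 (adjusted p = 0.0971 and 0.488), and with 75th percentile scaling (0.346). The median was -2.00 without KO replicate 2, -0.34 without KO replicate 3 and -0.67 and -0.66 without WT replicates 2 and 3. Cyp2b9, the first of them by size, differed by -2.99 (adjusted p = 0.363), and by -4.79 without KO replicate 2 and -1.14 without KO replicate 3. Genes biased to male liver had a median of -0.31, with 12 of 18 negative (camera adjusted p = 0.305). The hepatocyte list fell as well (median -1.21), so an effect of sex on these genes cannot be told apart from the hepatocyte level. Leaving out KO replicate 2 gave 1949 genes past the threshold, 1671 higher and 278 lower, and Notch1 then had an adjusted p of 0.0180, within a range of 0.00945 to 0.288 over the alternatives. Leaving out WT replicate 1 gave 60, 5 higher and 55 lower, and limma's array weights, which gave these arrays the lowest weights (0.315 and 0.274), gave 5744, 3905 higher and 1839 lower. Of the 31 genes named for this comparison, 23 passed without KO replicate 2 (adjusted p from 0.0145 to 0.0471). Without WT replicate 1, 3 passed: Ackr1 (adjusted p = 0.0446), Gzma (0.00343) and Cd3g (0.0446). Scaling each array to its 75th percentile moved the median of all genes to -0.18 and left 0 genes past the threshold.

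**Figure D2:**
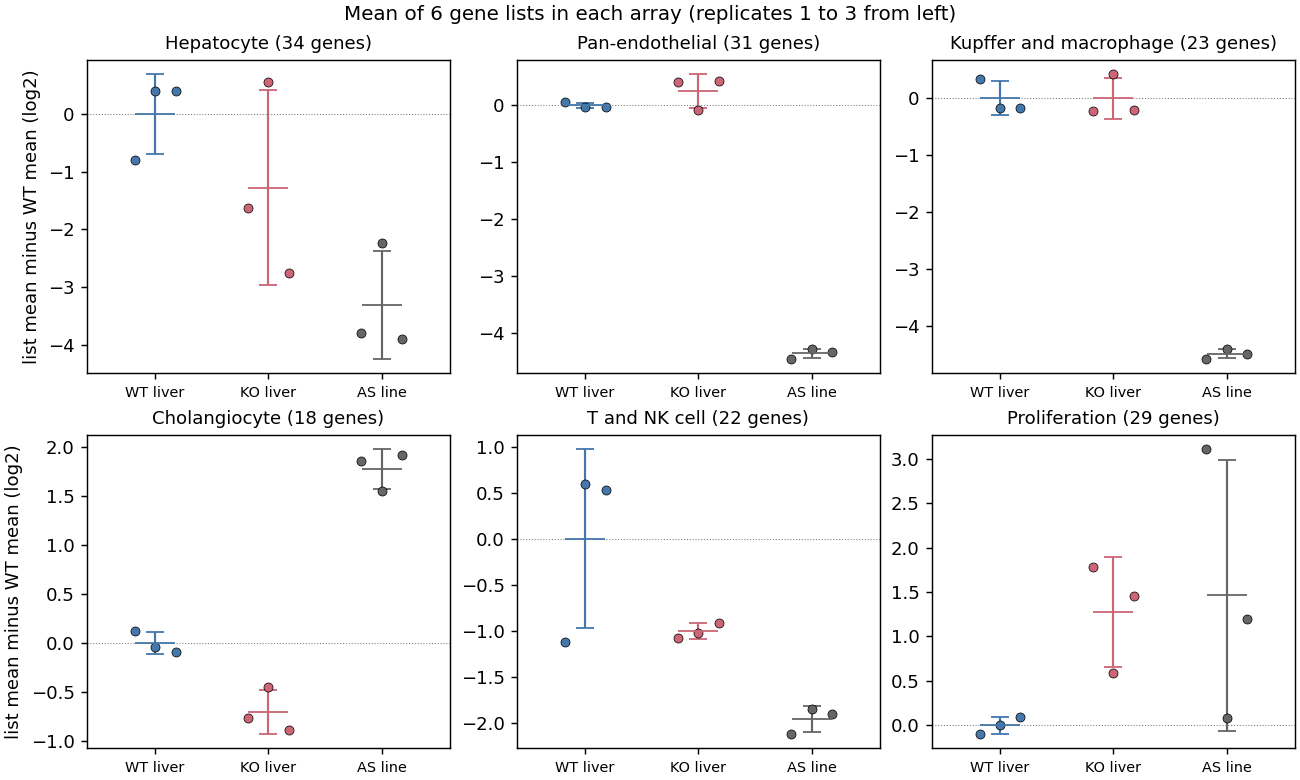
Mean log2 expression of 6 gene lists in each array, minus the mean of the WT livers (vertical axes, each with its own range). Points are arrays, in the order of replicates 1 to 3, horizontal bars group means and error bars 1 SD (n = 3). The hepatocyte list spans -2.75 to 0.56 in the KO livers, the pan-endothelial list lies at -4.45 to -4.29 in the cell lines, and the cholangiocyte list at 1.55 to 1.92.

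The AS cell lines were compared with the KO livers, which share their Notch1 genotype; this also sets cultured cells against samples of an organ. Endothelial genes were far lower in the lines, and 10 of 18 cholangiocyte genes were higher. Of 31 pan-endothelial genes, 30 fell over all genes tested and 31 adjusted over the list alone, with a median log2 fold change of -4.58. The cadherin of endothelial junctions, Cdh5, fell from 12.91 ± 0.16 to 5.52 ± 0.11 (SD, n = 3 each), a log2 change of -7.38 (SE 0.113, adjusted p = 1.66e-05). The receptors for vascular growth factors and angiopoietins Kdr and Tek fell by 7.01 (SE 0.148) and 6.58 (SE 0.154) on the log2 scale.

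Over all genes, 4275 passed the threshold, of which 2268 were higher and 2007 lower in the lines. At least a 2-fold change was seen in 1218 of the higher and 1420 of the lower genes. Leaving out KO replicate 1 or KO replicate 3 reduced the total to 2281 or 2310, the latter with 1023 higher and 1287 lower. Camera called 26 of 44 lists, 3 higher and 23 lower, and 0 with an estimated correlation, where the smallest adjusted p was 0.156. The self-contained test fry called 20 lists, 19 of them among the 26.

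Sinusoidal endothelial genes were low in the lines as well, with 19 of 24 lower over all genes, 20 adjusted over the list alone and a median of -5.29. The adjusted p was 0.156 with an estimated correlation, and 0.198 for the pan-endothelial list. The nuclease gene Dnase1l3 fell by 8.07 on the log2 scale (SE 0.111), the scavenger receptor Mrc1 by 7.56 (SE 0.113) and Gpr182 by 7.11 (SE 0.123). Of 19 genes named in angiosarcoma, 10 fell and 1 rose over all genes, and 11 and 2 adjusted over the list alone (adjusted p = 0.198 with an estimated correlation). The median was -0.56, and the members of largest change were Kdr, Tek and the endothelial receptor kinase Tie1, which fell by 5.62 (SE 0.194).

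Genes of bile duct epithelium formed the list with the highest median of those called. Of 18 cholangiocyte genes 10 rose and 0 fell, over all genes and adjusted over the list alone alike, with a median of 2.95 (camera adjusted p = 5.60e-05, and adjusted p = 0.239 with an estimated correlation). The keratin Krt19 rose from 5.74 ± 0.08 to 11.98 ± 0.18 (SD, n = 3 each), a log2 change of 6.24 (SE 0.115, adjusted p = 2.44e-05). The membrane protein gene Tspan8 rose by 5.67 (SE 0.303) and the keratin Krt7 by 5.54 (SE 0.466). Genes with still larger rises were Sprr1a, a component of stratified epithelium, at 6.29 (SE 0.113), and S100a6, a calcium-binding protein, at 6.25 (SE 0.195). Msln, a surface protein of mesothelium, rose by 5.88 (SE 0.211).

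Macrophage, pan-leukocyte and MHC class II genes were low in the lines. Of 23 Kupffer cell and macrophage genes, 22 fell, over all genes and adjusted over the list alone, with a median of -5.05 (adjusted p = 0.198 with an estimated correlation). The complement receptor gene Vsig4 fell by 8.06 (SE 0.140), Cd5l by 7.26 (SE 0.253) and the lysozyme gene Lyz2 by 7.08 (SE 0.226). All 16 pan-leukocyte genes fell under both adjustments (median -3.86, adjusted p = 0.198 with an estimated correlation), led by Arhgdib with -5.96 (SE 0.274). All 7 genes of antigen presentation by MHC class II fell under both (median -4.20, adjusted p = 0.239 with an estimated correlation), with Cd74 at -7.01 (SE 0.203) and H2-Aa at -6.86 (SE 0.215).

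Genes of inflammatory and immediate responses fell as well. Of 27 interferon-stimulated genes, 22 fell over all genes and 25 adjusted over the list alone, with a median of -2.43 (adjusted p = 0.244 with an estimated correlation). The chemokine Cxcl10 changed by -5.90 (SE 0.292, adjusted p = 2.54e-04). The GTPase Iigp1 changed by -4.98 (SE 0.839, adjusted p = 0.0131), a call that ended without KO replicate 1 (adjusted p = 0.0546) or KO replicate 3 (adjusted p = 0.0581). Of 28 chemokines and cytokines, 17 fell and 2 rose over all genes, and 18 and 4 over the list alone (median -2.69, adjusted p = 0.239 with an estimated correlation), with Ccl3 at -7.23 (SE 0.272) and Il1a at -7.18 (SE 0.232). Of 19 immediate early and handling-stress genes, 15 fell over all genes and 17 over the list alone (median -2.34, adjusted p = 0.198 with an estimated correlation). The transcription factor genes Fosb and Fos changed by -5.49 (SE 0.255) and -4.23 (SE 0.528).

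**Figure D3:**
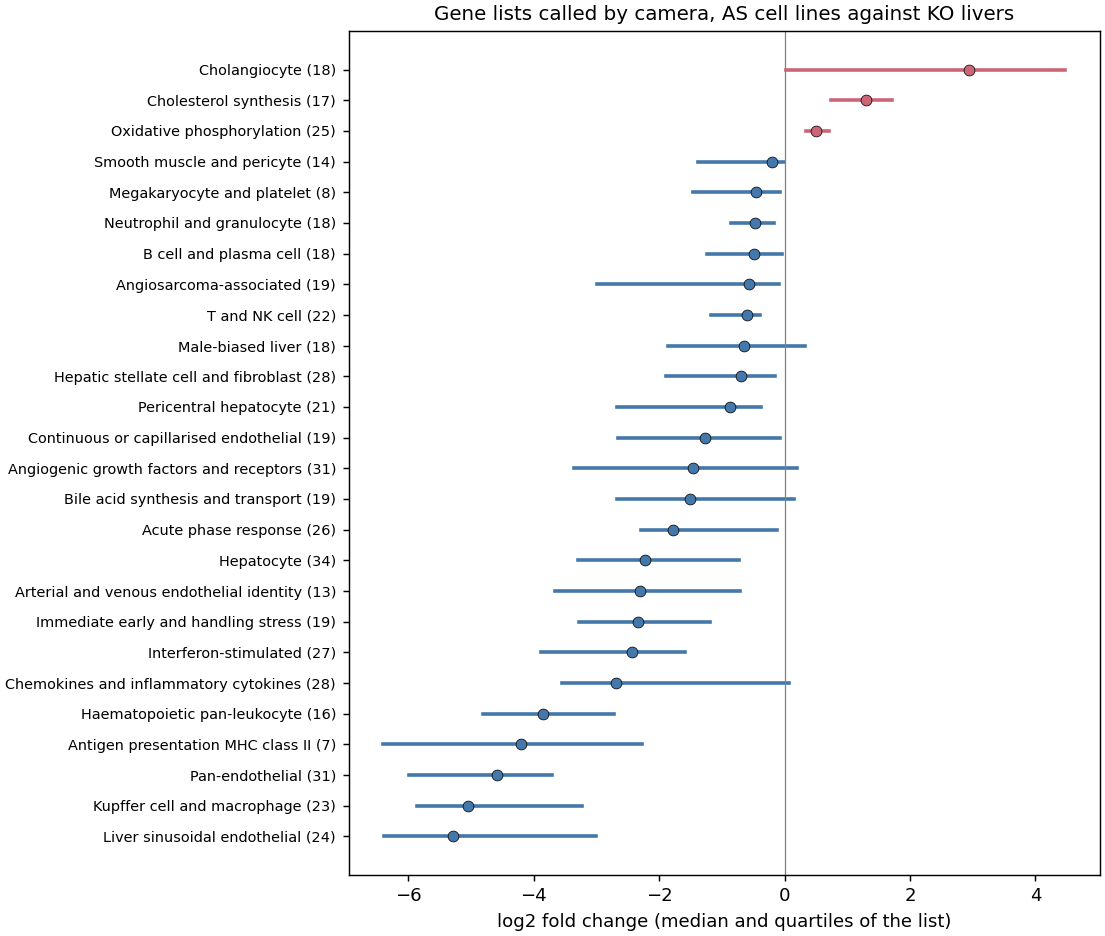
Log2 fold change between AS cell lines and KO livers (horizontal axis) for the 26 gene lists that camera called with a preset correlation, with the number of measured genes in brackets. Points are list medians and lines run from the lower to the upper quartile of the list; red is higher and blue lower in the lines. The medians run from -5.29 for sinusoidal endothelial genes to 2.95 for cholangiocyte genes, and 0 of the lists were called with an estimated correlation.

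Mesenchymal and hepatocyte genes changed in part. Of 28 stellate cell and fibroblast genes, 12 fell and 1 rose over all genes, and 17 and 1 over the list alone (median -0.70, adjusted p = 0.334 with an estimated correlation). The matrix proteoglycan gene Dcn changed by -6.49 (SE 0.269) and the growth factor gene Hgf by -5.65 (SE 0.229). In the hepatocyte list 4 of 34 fell and 0 rose under both adjustments, with a median of -2.23 (camera adjusted p = 1.32e-04, and adjusted p = 0.743 with an estimated correlation). These include Cyp2e1, a pericentral cytochrome P450, at -6.70 (SE 0.654), and the apolipoprotein gene Apoa2 at -5.00 (SE 0.755). The mean of the list ran from 8.84 to 12.16 within the KO livers, and the median was -1.13 without KO replicate 2. Of 20 genes of epithelial or endothelial to mesenchymal transition, 3 rose and 5 fell over all genes, and 4 and 8 over the list alone, and camera did not call the list (adjusted p = 0.187) while fry did (adjusted p = 0.0401). Tgfb2 rose by 3.63 (SE 0.277) and the cadherin Cdh2 by 3.27 (SE 0.491), while Tgfb1 changed by -2.51 (SE 0.147).

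Genes of metabolism and growth changed in part. All 25 genes of oxidative phosphorylation had positive log2 fold changes (median 0.51), of which 7 rose over all genes and 11 over the list alone (camera adjusted p = 2.25e-05, and adjusted p = 0.603 with an estimated correlation). Cytochrome c (Cycs) rose by 1.13 (SE 0.131, adjusted p = 0.00401; with the mean of its probe sets 0.51, adjusted p = 0.0992). Atp5o had a log2 fold change of 0.90 (adjusted p = 0.0125), and its call ended without KO replicate 1 (adjusted p = 0.0575) or KO replicate 3 (adjusted p = 0.0571). Of 17 cholesterol synthesis genes 2 rose over all genes and 7 over the list alone (median 1.30, camera adjusted p = 0.00691). This call was lost without AS replicate 1 (adjusted p = 0.0807) and had adjusted p = 0.743 with an estimated correlation. The lanosterol synthase gene Lss had a log2 fold change of 2.55 (SE 0.678, adjusted p = 0.0521; 0.0408 without KO replicate 2 and 0.0333 without AS replicate 3). It passed under 7 further alternatives that keep all arrays, the replicate block among them (adjusted p from 0.0181 to 0.0452). Of 17 fatty acid synthesis genes 2 rose over all genes and 1 over the list alone (camera adjusted p = 0.141, and 0.00320 without KO replicate 2). Malic enzyme (Me1) rose by 4.04 (SE 0.783, adjusted p = 0.0202), with adjusted p-values from 0.0549 to 0.0784 when KO replicate 1 or 3 or any 1 of the lines was left out. Of 19 endoplasmic reticulum stress genes 2 rose and 1 fell, under both adjustments (camera adjusted p = 0.882, median 0.02 with the direction of the test down), with the asparagine synthetase gene Asns at 4.08. Of 29 proliferation genes 1 rose under both adjustments, the ribonucleotide reductase subunit gene Rrm2 by 3.00 (SE 0.320), and Mcm3 had a log2 fold change of -1.21 (SE 0.707, adjusted p = 0.304; without AS replicate 1 -1.93, adjusted p = 0.0414; without AS replicate 2 -0.60, adjusted p = 0.565). Camera did not call that list (adjusted p = 0.898); its median was 0.19 while the direction of the test was down. Without AS replicate 1 it was called lower, with a median of -0.70 and an adjusted p of 0.00203.

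Notch1 did not differ detectably between the lines and the KO livers, with a log2 difference of 0.03 (SE 0.344, adjusted p = 0.971) and a mean of 8.39 ± 0.50 (SD, n = 3) in the lines. Of 11 Notch receptors and ligands, 3 rose and 3 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.536). The endothelial ligand Dll4 changed by -3.67 (SE 0.265, adjusted p = 8.53e-04) and Notch4 by -2.78 (SE 0.242, adjusted p = 0.00159), while Jag1 rose by 3.02 (SE 0.249, adjusted p = 0.00134). Of 21 Notch target genes 2 rose and 3 fell over all genes, and 3 and 3 over the list alone (camera adjusted p = 0.898). Sox9 rose by 3.05 (SE 0.203, adjusted p = 6.53e-04) and Mfng changed by -2.77 (SE 0.221, adjusted p = 0.00119).

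The AS cell lines and the WT livers form the third pair of groups in the design. Here 31 of 31 pan-endothelial genes fell under both adjustments, with a median of -4.29, and camera called this list also with an estimated correlation (adjusted p = 0.0391). Dnase1l3 changed by -8.19 (SE 0.118), Cdh5 by -7.26 and Kdr by -6.84. Of 18 cholangiocyte genes 10 rose and 2 fell under both adjustments (median 2.01, camera adjusted p = 0.00919, and adjusted p = 0.42 with an estimated correlation). Tspan8 rose by 5.56 and Krt19 by 5.52 (SE 0.178), and the largest rises over all genes were those of S100a6, at 5.79 (SE 0.338), and Msln, at 5.76 (SE 0.207). In all, 5715 genes passed the threshold, 3506 higher and 2209 lower. Scaling each array to its 75th percentile gave 2476 higher and 2884 lower, 46.2% higher against 61.3%, and moved the median of all genes to -0.19 from 0.02. Without WT replicate 2 or 3 the total was 3397 or 3556.

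Hepatocyte genes were lower than in the WT livers, with 20 of 34 lower and 0 higher over all genes and 24 lower over the list alone (median -3.50, camera adjusted p = 1.06e-10, and adjusted p = 0.391 with an estimated correlation). Cyp2e1 changed by -7.77 (SE 0.210) and Hpd, an enzyme of tyrosine breakdown, by -6.24. Of 23 Kupffer cell and macrophage genes 22 fell under both adjustments (median -5.09, adjusted p = 0.137 with an estimated correlation), with Vsig4 at -8.06 and Lyz2 at -7.27. The proliferation list had 26 of 29 positive log2 fold changes and a median of 1.56, with 1 gene, Rrm2 (3.94), higher under both adjustments. Its camera call (adjusted p = 0.00855) was lost without AS replicate 1 (median 0.72, adjusted p = 0.108), with dim genes left out (0.101) and with an estimated correlation (adjusted p = 0.713). Of 19 genes of DNA damage and p53 response 8 rose and 4 fell over all genes, and 9 and 4 over the list alone (camera adjusted p = 0.194, and 0.0481 with 75th percentile scaling; fry adjusted p = 0.0427). The death receptor gene Fas changed by -3.66, and the p53 targets Phlda3 and Zmat3 rose by 3.03 and 2.52.

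Notch1 was lower in the lines than in the WT livers by a log2 difference of -3.08 (SE 0.315, adjusted p = 0.00159). Of 11 Notch receptors and ligands 3 rose and 4 fell under both adjustments (camera adjusted p = 0.131, fry adjusted p = 0.00595), with Dll4 at -3.43 and Jag1 at 2.30. This list includes Notch1 itself and was not tested without it. Of 21 Notch target genes 3 rose and 2 fell under both (camera adjusted p = 0.841, median 0.03 with the direction of the test down), with Sox9 at 2.20.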

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

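The tests with a hepatocyte covariate, and without WT replicate 1 and KO replicate 3 together, were chosen only after the result was seen. Between KO and WT livers 0 genes passed, against 2 with all 9 arrays in one fit, 5744 with array weights, 366 at an adjusted p under 0.10 and 0 to 1949 with 1 replicate left out. Notch1 differed by -3.05 with array weights and by -3.33 to -2.84 with 1 replicate left out. Between AS lines and KO livers 2638 genes changed at least 2-fold, and 2281 to 4048 passed with 1 replicate left out. Between AS lines and WT livers these values were 3492 and 3397 to 5435. The replicate numbers were not taken as pairs. After group means were subtracted, arrays of equal number had correlations from -0.39 to 0.43. The best correlation with another number ran from -0.26 to 0.47. With 3 arrays per group these values cannot show whether the samples are paired. With a replicate block 0, 3426 and 4494 genes passed in the 3 comparisons, and the proliferation list in AS lines against KO livers had a median of 0.19 with the test turned upward, the fatty acid synthesis list was called higher (adjusted p = 0.0410) and Lss passed (adjusted p = 0.0181). The direction of weak results turned. In KO against WT livers without WT replicate 1 and KO replicate 3, Eif2s3y was at -0.0017, Uty at -0.0066, the Kupffer list at 0.26 and the stellate list at -0.0698. With dim genes left out the test turned for the sinusoidal list (0.13), the interferon list (0.0626) and the stellate list (0.0713). Scaling to the 75th percentile turned the test of the Kupffer list (median -0.20), and repeated quantile normalization those of the interferon (0.0242) and stellate (-0.0478) lists. Camera sets a list against all other genes, so its direction can turn while the median of the list keeps its sign. With 1 replicate left out the Kupffer list ran from -0.21 to 0.18, the interferon list from -0.0283 to 0.21 and the stellate list from -0.0492 to 0.17. In AS lines against KO livers, Notch1 was at -0.004 after 75th percentile scaling and at -0.24 to 0.31 with 1 replicate left out. The test of the proliferation list turned with dim genes left out (0.21), with 75th percentile scaling (0.16) and with fry (0.19), and its median ran from -0.70 to 0.91 with 1 replicate left out. The Notch target list ran from 0.0293 to 0.18, and the endoplasmic reticulum stress list from -0.17 to 0.20 with fry at 0.0179. In AS lines against WT livers the Notch target list ran from -0.0461 to 0.10. Over the 19, 20 and 8 lists followed in the 3 comparisons, in the order above, camera calls were lost in 43, 17 and 7 combinations of list and alternative, the estimated correlation and fry included; the cause was not tested. With 3 arrays per group, and without detection calls, changes near background are measured least well.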

Other observations

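The tests of causes for the hepatocyte, cell cycle and AS line patterns, and the counts over splits, were chosen only after the result was seen, while leaving out each replicate was planned. The genes Alb, Ttr, Hnf4a, Afp, Ahsg, Epcam, Cdh1, Krt8, Xist and Mki67 were chosen after their values were seen. The 3 lines differed among themselves. The mean of the proliferation list ranged over 3.03 log2 units in the lines, 8.15-fold, and the proliferation gene Mki67 stood at 10.77, 6.79 and 8.88 in AS replicates 1, 2 and 3. Of plasma protein genes, albumin (Alb) stood at 12.31, 13.67 and 12.82 and transthyretin (Ttr) at 12.42, 12.91 and 12.49, within the liver ranges of 12.14 to 13.96 and 10.485 to 13.41. The low end of both ranges came from KO replicate 3, where the hepatocyte list was lowest. In the WT livers Alb ran from 13.835 to 13.96, above all 3 lines. Neither differed detectably from the KO livers (adjusted p = 0.819 and 0.615) or the WT livers (0.0932 and 0.132). The fetal liver gene Afp stood at 10.63 in AS replicate 2 and at 6.38 and 5.75 in AS replicates 1 and 3, against 5.46 to 5.75 in the livers. Ahsg, a further plasma protein gene, stood at 7.11, 13.44 and 7.23. Xist, the RNA of the inactive X chromosome, stood at 4.96 in KO replicate 3 and from 11.46 to 12.29 in the other 8 arrays.

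The mean of the hepatocyte list ranged over 3.32 log2 units in the 6 livers, 9.98-fold, while the pan-endothelial list ranged over 0.52. The sex of 1 KO animal is argued against as the whole cause, since the 5 arrays without Y-linked signal still spanned 2.19. The cell makeup of the samples may differ, though a change of state of the hepatocytes would give the same. Of 118 genes of other hepatic functions, 57.6% were lowest in KO replicate 3, where the hepatocyte list was lowest, against 16.7% with no order. These genes also serve hepatic functions and are not independent of each other, so this share cannot decide between the 2. An equal effect of Notch1 loss in all KO livers is argued against as the cause of the range. The lowest and highest arrays, KO replicates 3 and 2, both had low Notch1 (8.52 and 8.75). A part of Notch1 loss in the lower KO mean cannot be told apart from sample makeup. The KO minus WT difference of the list means was -1.27 with overlapping groups (exact permutation p = 0.4).

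Of 29 cell cycle genes 28 had positive log2 fold changes in the KO livers, but 0 passed over all genes, and the camera call of the list was lost (adjusted p = 0.83 with an estimated correlation, and 0.309 with fry). A lower hepatocyte share that raises all other transcripts alike is argued against: the medians of 5 other cell type lists ran from -0.26 to 0.19, below the lower quartile of the proliferation list at 0.97. The sex of 1 KO animal is argued against as well, with a median of 1.26 without KO replicate 3. Loss of Notch1 may contribute and stays open beside MxCre, which only the KO mice carried, and unrecorded differences between the animals. The exact permutation p for the list means was 0.1, the smallest that 3 against 3 arrays allow.

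The AS lines had low pan-endothelial genes and high levels of 10 of 18 cholangiocyte genes, although the labels derive them from hepatic endothelial cells. Normalization of unlike arrays is argued against, since quantile normalization keeps the order of values within an array and the median rank of the pan-endothelial genes was at least 53.5 percent points lower in each line than in each KO liver. Cells of an epithelial lineage may make up the lines, with a pan-endothelial level of 4.18% of that in the KO livers. This cannot be told apart from endothelial cells that lost endothelial genes and acquired both cholangiocyte and hepatic genes. Of the 18 cholangiocyte genes, 2 are in another list. The epithelial cadherin Cdh1 stood at 11.43, 10.96 and 11.64 against 6.48 to 8.43 in the livers (adjusted p = 2.14e-04 against KO and 3.35e-04 against WT livers). Krt8, which hepatocytes also express, rose by 3.68 over the KO livers (adjusted p = 0.0212) and by 1.85 over the WT livers (0.00102). Cdh1 and Krt8 both belong to the cholangiocyte list, so they are not evidence apart from it. Alb and Ttr were within the liver ranges, so a gain of cholangiocyte genes alone would not describe the lines. The hepatic transcription factor gene Hnf4a stood at 10.95, 11.10 and 10.35 against 7.16 to 10.53 in the livers, so that 1 line did not reach the highest liver, and the epithelial gene Epcam was at 5.56 to 6.02 and did not differ detectably from the KO livers (adjusted p = 0.121) or the WT livers (0.291).

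With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. Between KO and WT livers the real split gave 0 genes, so that 10 of 10 splits necessarily gave as many, and the highest of the others gave 654. At an unadjusted p under 0.05 the real split had 4479 genes and the highest of the others 2621. The split with 654 sets WT replicate 1, KO replicate 1 and KO replicate 3 against the rest and points to a structure of the samples. KO replicate 2 had correlations of 0.986 and 0.987 with WT replicates 2 and 3, and of 0.974 and 0.967 with KO replicates 1 and 3. WT replicate 1 had correlations of 0.954 to 0.970 with the other livers. A difference in sampling was not tested. Notch1 stood at 11.69 in WT replicate 1, against 11.02 and 11.71 in the other WT livers. In KO replicate 2 it stood at 8.75, against 7.84 and 8.52 in the other KO livers. These values argue against an exchange of these 2 samples between the genotypes. Between AS lines and KO livers 1 of 10 gave as many as the real 4275, with 0 as the highest other, and between AS lines and WT livers 1 of 10 gave as many as the real 5715, also with 0.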
